A study of Mus musculus with 10 samples.

How the data were processed

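RNA from 10 libraries of mouse embryonic stem cells was sequenced single-end, per the labels' protocols, from libraries made with the Illumina TruSeq protocol. The groups were WT and KO (cells with floxed Mof alleles and inducible Cre, given ethanol or 100 nM 4-hydroxytamoxifen for 3 days, without a statement of which group had which), and Control (water), ETO (etomoxir for 4 days) and Released (4 more days without etomoxir) in E14tg2a cells. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.1 to mm10, with SAMtools 1.5 and deepTools also named, and the program that made the gene tables is not stated. Strand use in counting is not given, so genes that overlap or lie antisense to each other, such as Xist and Tsix, are uncertain.

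The deposited gene table holds, per the file headers, a count for each gene and library. Tests on its low values (under 20 reads) showed that the deposited signal is a read count divided by 1 factor per library, with steps of 0.689 to 1.35 normalised counts per read. Within a tolerance of 0.1 read, 84.4% to 85.6% of all values and 88.9% to 90.2% of low values were whole reads, so the values are not whole read counts and no count model was fitted to them. The deposited FPKM table, per the file headers, holds FPKM values, which carry the same factor per library as the deposited counts. The table has 50273 rows, of which 1314 merge more than 1 gene and hold 11.5% to 14.4% of the signal. Values of rows with the same gene name were summed.

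The normalised counts were kept on the authors' scale, as log2(value + 1), which makes changes of weakly expressed genes smaller than their ratios. Genes with a value of at least 10 in at least 2 libraries were tested. A linear model with 1 mean per group over all 10 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, an intensity trend and robust fitting. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison, with two-sided tests. The comparisons were KO against WT, ETO against Control, Released against ETO, Released against Control, and the difference between the KO and ETO changes. The edgeR quasi-likelihood test, planned as the main test before the data were examined, was not used, because the deposited values are not whole read counts. The rest of the plan, including the gene lists, the rule for named genes and most alternatives, was also made before the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures.

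A row of mt-Atp6 to mt-Nd5 and the row of mt-Nd6 were listed at 0 in Released replicate 1 and at 218611 and 15492 in Released replicate 2. They were left out of all tests after this was seen, and their changes come from a fit without Released replicate 1. The share of mitochondrial rows in Released replicate 1, 1.71% against 3.71% in replicate 2, lacks them.

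In all, 36 gene lists with 951 entries were fixed, and 908 of the entries had a row in the table. Lists with at least 5 tested members, 34 of them, were tested with camera at a preset correlation of 0.01, adjusted over 136 tests of lists and 4 comparisons. Camera compares a list with the other genes. Of the tests, 63 were called so, and 25 with a correlation estimated per list. Fry, which asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes, called 110. Camera tests of the difference between KO and ETO changes were adjusted separately.

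The rule for named genes took, per comparison, the 8 rising and 8 falling genes with the largest fitted change among called genes with a mean CPM of at least 5 in the higher group and both replicates of a group beyond both of the other. Names of predicted genes were passed over. From each list it took up to 4 members with the smallest adjusted p, and always Kat8, Cpt1a, Cpt1b, Cpt1c and Cpt2. The rule also took the 5 largest differences between KO and ETO changes in each direction, and genes of the largest ETO changes still called after release. The examples printed were picked from the genes so named after their values were seen, with preference for those whose calls held under the alternatives. Some genes that the rule took are not reported here.

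The procedure was tested on simulated data drawn from the real means, with 200 genes changed per draw and 20 draws per comparison. Each gene had the same spread in all groups, unlike the real replicates, and far fewer genes changed than were called in the real data. The rates below thus hold for the simulated setting, and false calls from unequal spreads could not show. It recovered 73.0% of 2-fold changes for KO against WT, 72.4% for ETO against Control, 71.4% for Released against ETO and 71.6% for Released against Control, with 15555 to 15809 genes tested per draw. Recovery of 1.5-fold changes was 52.3%, 53.1%, 51.7% and 52.9%, and of 4-fold changes 87.3%, 86.4%, 86.8% and 86.0%, in the same order. The share of false calls was above the nominal 5%: 358 of 3143 calls (11.4%) for KO against WT, 194 of 2950 (6.58%) for ETO against Control, 167 of 2923 (5.71%) for Released against ETO and 270 of 3031 (8.91%) for Released against Control. Of these false calls, 136, 53, 37 and 94 fell on genes with a baseline under 10 in the compared groups. Draws without changed genes gave a median of 2, 0, 0 and 0 calls, and at most 7, 2, 2 and 7.

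Alternatives covered the scaling (median-of-ratios factors, TMM factors with and without mitochondrial and the 20 highest genes, total signal), the filter (none, or CPM above 1), a fold threshold, a fit per experiment, a replicate block, the FPKM table with pseudocounts of 1 and 0.1, and each library left out in turn. The pseudocounts of 0.5 and 5, repeated names kept apart and the mitochondrial rows kept were chosen after seeing the data. So were separate ETO libraries, a correction for gene length and GC content, and plain TMM factors in this fit.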

Results

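RNA was sequenced from mouse embryonic stem cells grown in 2i/LIF medium, which holds inhibitors of MEK and GSK3 and the cytokine LIF. The first experiment used cells with floxed Mof alleles and a tamoxifen-inducible Cre recombinase, in a wild type group (WT) and a Mof knockout group (KO). Mof is the gene Kat8, which encodes a histone acetyltransferase. The second experiment used the E14tg2a line with water (Control), with etomoxir for 4 days (ETO), or with etomoxir followed by 4 days without it (Released). Etomoxir inhibits the carnitine palmitoyltransferases of the CPT1 family, which bring long-chain fatty acids into mitochondria for oxidation. Each of the 5 groups had 2 libraries, which the labels call biological duplicates, so the p-values measure only the spread between these samples. The normalised counts of a library summed to between 10562100 and 13326200, from an estimated 9783480 to 16778600 reads. A count of 3 reads, the upper limit that a count of 0 allows, corresponded to normalised counts of 2.07 to 4.04, a limit that covers counting error only. A total of 16056 genes were tested, and replicates correlated across genes with Pearson's r of 0.985 to 0.990 on the log2 scale (genes are not independent replicates). The median absolute log2 difference between replicates was 0.183 in WT, 0.147 in KO, 0.106 in Control, 0.120 in ETO and 0.105 in Released. The model shares 1 spread per gene over all groups, so it can understate the error of KO against WT. It can likewise overstate the error of the comparisons within the E14tg2a line.

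**Figure D1:**
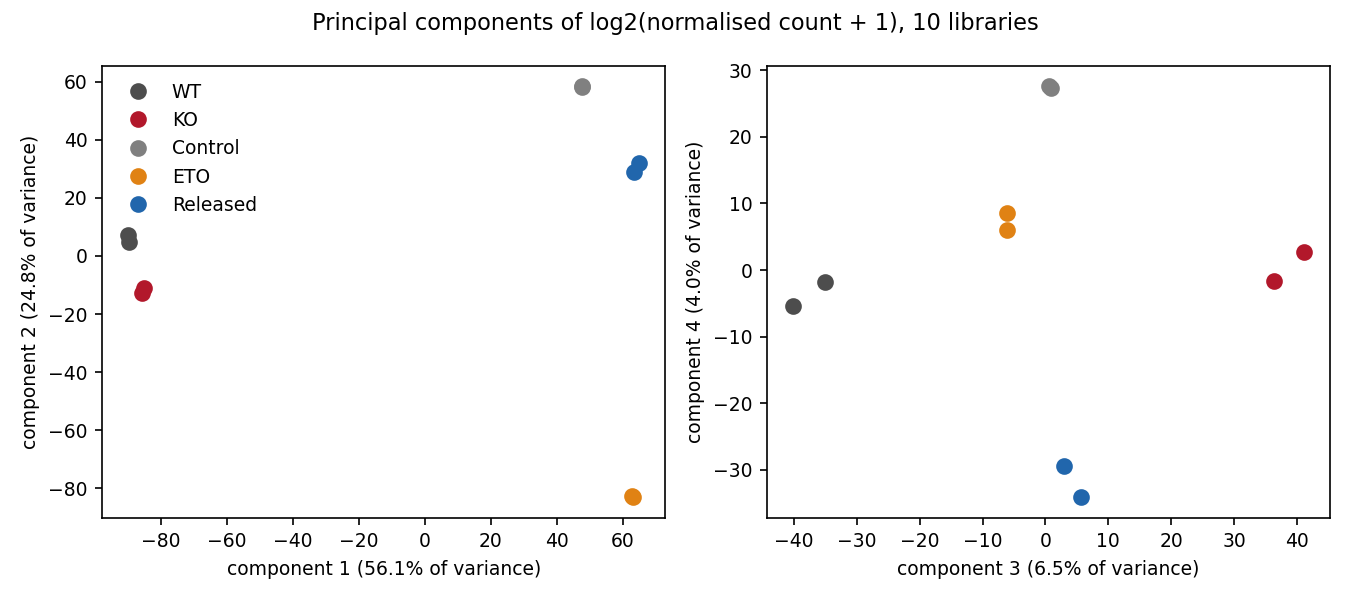
Principal components of log2(normalised count + 1) for the 10 libraries, coloured by group, with component 1 against 2 and component 3 against 4. Component 1 held 56.1% and component 2 held 24.8% of the variance.

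The first comparison, KO against WT, asks which transcripts differ between the Mof knockout and wild type groups. The labels name no group with hydroxytamoxifen or active Cre but intact Mof. Any effect of the drug or of Cre activity is thus not separated from that of Mof loss. Kat8 itself, on chromosome 7 from 127912516 to 127925837 (mm10), measured 433 and 357 normalised counts in the WT libraries and 222 and 205 in the KO libraries. It measured 372 and 383 in Control, 566 and 529.7 in ETO, and 339 and 395 in Released. In KO it fell by 0.88 on the log2 scale (SE 0.11, adjusted p = 3.64e-05), and the gene total does not separate the deleted exons from the rest. Cpt1a, the form of CPT1 found in liver and many other tissues, went from 3633 ± 62.0 to 2951 ± 31.8 (log2 change -0.30 ± 0.06 SE, adjusted p = 0.00086) (means ± SD of normalised counts, n = 2, as for all such pairs below). Cpt2, which acts after CPT1 on the inner mitochondrial membrane, went from 315 ± 19.2 to 229 ± 17.1 (log2 change -0.46 ± 0.11 SE, adjusted p = 0.00445), a call lost in the FPKM values. Cpt1c, the brain form, had a log2 change of 0.27 (adjusted p = 0.0117), a call lost under other scalings, in the FPKM values and without WT replicate 2 or KO replicate 1. The row that merges Chkb and Cpt1b, whose genes overlap so that the source of its reads is uncertain, rose (0.75, adjusted p = 9e-06).

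**Figure D2:**
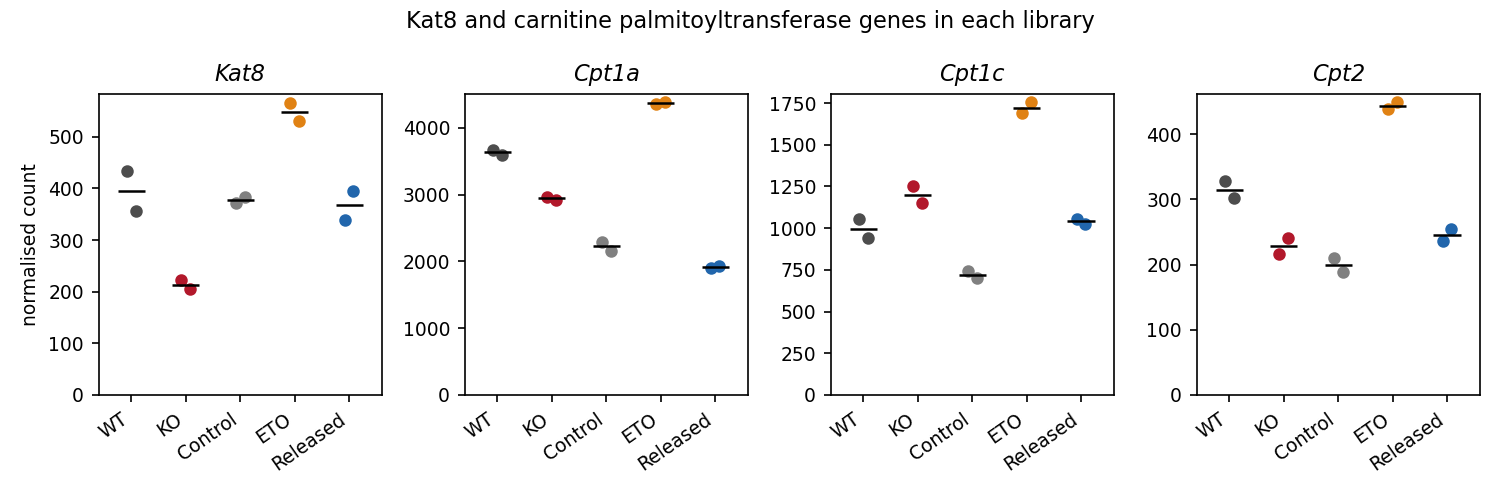
Normalised counts of Kat8, Cpt1a, Cpt1c and Cpt2 in each library, as points, with a line at the mean of each group (n = 2). Kat8 lay at 222 and 205 in KO against 433 and 357 in WT, and Cpt1a had its highest values in ETO, with a mean of 4379.

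Genes of the amino acid and stress response under the transcription factor ATF4 rose in KO cells. Trib3, a pseudokinase induced by ATF4, went from 477 ± 56.9 to 1551 ± 13.1 (log2 change 1.70 ± 0.10 SE, adjusted p = 3.71e-08). Ppp1r15a, whose product directs dephosphorylation of eIF2-alpha, went from 625 ± 35.9 to 1459.7 ± 76.1 (log2 change 1.22 ± 0.08 SE, adjusted p = 8.12e-08). Atf4 itself rose by 0.75 on the log2 scale, and Hspa5, the endoplasmic reticulum chaperone BiP, went from 2415 ± 189.7 to 4660.3 ± 192 (0.95). Acadvl, the very long-chain acyl-CoA dehydrogenase of fatty acid oxidation, went from 228 ± 34.3 to 101 ± 12.4 (-1.16).

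The largest rises among the genes chosen by the rule for named genes were those of Ms4a10 (3.06), Prph (2.59), Gpnmb (2.51), Cox6a2 (2.51), Cpne2 (2.50), Krt19 (2.48), Perp (2.41) and Serpine2 (2.38), with log2 changes in parentheses, as for other genes below. Krt19 was counted in a row merged with a predicted gene. Gpnmb, a lysosomal membrane glycoprotein, went from 81.8 ± 4.67 to 471 ± 26.0, and Serpine2, a secreted protease inhibitor, from 131 ± 1.29 to 683 ± 29.9. The largest falls were those of Itgal (-3.26), Tnni1 (-2.47), Pdk2 (-2.38), Pold4 (-2.34), Arpin (-2.28), Sema4f (-2.18) and Il17rc (-2.18) and of the merged row of H2-DMb1 and H2-DMb2 (-3.12). Of these, Pdk2, Sema4f and Il17rc were not called in the FPKM values. Itgal, an integrin alpha chain, went from 159 ± 5.30 to 16.0 ± 4.06, and Pold4, a subunit of DNA polymerase delta, from 156 ± 19.8 to 29.9 ± 0.360.

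Of 31 measured ATF4 and amino acid response genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone). The ATF4 and amino acid response genes stood above other genes as a list (camera adjusted p = 4.68e-09, adjusted p = 0.0286 with an estimated correlation). Of 19 chaperone and unfolded protein response genes of the endoplasmic reticulum, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with rises of Calr (0.74), Xbp1 (1.01) and Herpud1 (0.93). The chaperone and unfolded protein response genes of the endoplasmic reticulum stood above other genes as a list (camera adjusted p = 8.38e-06, adjusted p = 0.04 with an estimated correlation). Of 22 NRF2 and oxidative stress genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with rises of Nqo1 (0.76), Srxn1 (0.84), Sod2 (0.50) and Gclc (0.58). The NRF2 and oxidative stress genes stood above other genes as a list (camera adjusted p = 0.000192, adjusted p = 0.0431 with an estimated correlation). Of 28 p53 target genes, 15 rose and 1 fell (16 and 2 adjusted over the list alone), with rises of Perp (2.41), Ddit4 (1.01), Mdm2 (0.75) and Plk2 (0.79), of which Ddit4 is also on the ATF4 list. The p53 target genes stood above other genes as a list (camera adjusted p = 0.000163, adjusted p = 0.0823 with an estimated correlation). Of 28 Myc family and Myc target genes, 19 rose and 2 fell (19 and 2 adjusted over the list alone), with rises of Nop56 (0.58) and Ppan (0.74). The Myc family and Myc target genes stood above other genes as a list (camera adjusted p = 0.000627, adjusted p = 0.0629 with an estimated correlation). Of 71 cytosolic ribosomal protein genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone), with rises of Rpl10 (1.13) and Rpl3 (0.63). The cytosolic ribosomal protein genes stood above other genes as a list (camera adjusted p = 0.00924, adjusted p = 0.0577 with an estimated correlation), a call also lost with total signal as the factor. Of 34 ribosome biogenesis genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone), with rises of Utp4 (0.55) and Nop58 (0.78). The ribosome biogenesis genes stood above other genes as a list (camera adjusted p = 0.0196, adjusted p = 0.13 with an estimated correlation), a call lost under each other scaling, with a median that turned negative with total signal. Of 40 autophagy and lysosome genes, 16 rose and 3 fell (17 and 4 adjusted over the list alone), with rises of Sqstm1 (0.94), Atg9b (1.08) and Ctsl (0.50). The autophagy and lysosome genes stood above other genes as a list (camera adjusted p = 0.0335, adjusted p = 0.176 with an estimated correlation), a call lost under other scalings and in a fit per experiment, with a median that turned negative with total signal. Of 23 genes of mitochondrial fatty acid oxidation, 2 rose and 10 fell (2 and 10 adjusted over the list alone), with falls of Hadha (-0.43) and Acad9 (-0.49). The genes of mitochondrial fatty acid oxidation stood below other genes as a list (camera adjusted p = 0.00104, adjusted p = 0.052 with an estimated correlation). Of 14 genes of peroxisomal fatty acid oxidation, 0 rose and 4 fell (0 and 4 adjusted over the list alone), with falls of Hsd17b4 (-0.76) and Ehhadh (-0.98). The genes of peroxisomal fatty acid oxidation stood below other genes as a list (camera adjusted p = 0.033, adjusted p = 0.13 with an estimated correlation).

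Of 8 PPAR target genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.223), with a fall of Slc25a42 (-0.68). Of 15 genes of fatty acid synthesis, 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.817), with a rise of Fasn (0.75), the fatty acid synthase, and a fall of Acss2 (-0.70). Of 22 cholesterol synthesis genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.787), with a rise of Sqle (0.53) and a fall of Lss (-0.52). Of 23 glycolysis genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.593), with a fall of Pfkm (-0.58). Of 24 genes of the TCA cycle, 4 rose and 7 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.0989), with a rise of Cs (0.51), the citrate synthase. Of 67 nuclear genes of oxidative phosphorylation, 11 rose and 11 fell (11 and 11 adjusted over the list alone, camera adjusted p = 0.242), with a fall of Ndufv1 (-0.54). The 2 tested rows of mitochondrially encoded genes rose (2 and 0 adjusted over the list alone), mt-Cytb by 0.66 and the row of mt-Nd1, mt-Nd2 and both ribosomal RNAs by 1.06, and the first call was lost without WT replicate 1 or KO replicate 2. The other 2 rows were not called in KO, with log2 changes of 0.07 for the row of mt-Atp6 to mt-Nd5 (adjusted p = 0.713) and 0.40 for mt-Nd6 (adjusted p = 0.131), from a fit without Released replicate 1. Of 28 genes of the pluripotency network, 7 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.411), with rises of Nanog (0.35) and Zfp42 (0.41) and a fall of Esrrb (-0.41). Of 17 genes of formative and primed pluripotency, 9 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.176), with rises of Cdh2 (2.33), Lefty1 (2.31) and Nodal (0.93). Of 16 primitive endoderm markers, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.376), with a rise of Sparc (0.39). Of 12 trophectoderm markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.605), with a rise of Tfap2c (0.37). Of 11 mesoderm and primitive streak markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.795), with a rise of Eomes (1.27) that was lost in the FPKM values. Of 9 neural markers, 1 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.341). Of 10 fibroblast and feeder markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.85), with a rise of Vim (0.76). Of 20 germline genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.849), with a rise of Dazl (1.06). Of 24 imprinted genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.215), with rises of Rian (1.34) and Peg3 (0.81) and a fall of Slc38a4 (-0.60). Eif1a, the 1 measured member of the list of genes of 2-cell-like cells, rose by 0.76 on the log2 scale.

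Of 36 G1/S and replication genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.226), with a rise of Orc1 (0.71). Of 35 G2/M genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.416), with a rise of Ect2 (0.54) and a fall of Ccnb2 (-0.41). Of 27 cell cycle inhibitors and quiescence genes, 13 rose and 5 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.226), with rises of Gadd45a (1.11) and Ccng1 (0.53). Of 11 genes of MOF and its MSL and NSL complexes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.806), with a rise of Ogt (0.54) and a fall of Msl3 (-0.84) beside Kat8. Of 24 genes of other lysine acetyltransferases and deacetylases, 8 rose and 6 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.988), with falls of Hdac11 (-2.14), Hdac10 (-1.38) and Sirt2 (-1.19). Of 19 ERK signalling targets, 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.29), with a rise of Ier2 (0.99). Of 16 Wnt/beta-catenin targets, 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.928), with a rise of Ccnd1 (0.54). Of 14 interferon response genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.786), with a rise of Ifitm3 (0.45). Of 15 genes of the DNA methylation machinery, 7 rose and 1 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.242), with rises of Tet2 (0.55) and Zfp57 (0.42). With total signal as the factor, the medians of these lists changed sign: fatty acid synthesis, cholesterol synthesis, glycolysis, trophectoderm, G1/S, G2/M, MOF complexes, other acetyltransferases and deacetylases, and Wnt targets. The median, the mean and the test did not share a sign for PPAR targets, fatty acid synthesis, cholesterol synthesis, glycolysis, oxidative phosphorylation, neural and fibroblast markers, G2/M genes, MOF complexes, other acetyltransferases and deacetylases, and Wnt targets. Over all genes, 6086 passed an adjusted p of 0.05, 3944 rising and 2142 falling, and 1088 of them changed at least 2-fold (570 rising and 518 falling). The share of rising genes among the calls was 64.8% as deposited, 52.4% with median-of-ratios factors, 47.3% with TMM factors, 52.5% with TMM factors without mitochondrial genes and the 20 highest genes, and 37.3% with total signal as the factor. In the FPKM values 2906 genes were called, and in a fit per experiment 2842 rose and 1541 fell.

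The second comparison, ETO against Control, asks what follows when fatty acid oxidation is inhibited. Cell cycle genes fell in ETO: Ccnb2, a mitotic cyclin, went from 1509 ± 8.23 to 424 ± 20.6 (log2 change -1.83 ± 0.07 SE, adjusted p = 7.77e-12), and Uhrf1, which recruits the maintenance DNA methyltransferase, went from 6208 ± 37.2 to 2171 ± 128 (log2 change -1.52 ± 0.05 SE, adjusted p = 7e-12). Slc7a11, the cystine transporter, went from 13.8 ± 3.96 to 1120.4 ± 52.4 (6.27), Ddit3, the factor CHOP, from 88.0 ± 15.7 to 1509 ± 46.6 (4.09), and Pmaip1, the p53 target Noxa, from 27.9 ± 7.21 to 726 ± 10.2 (4.67). Krt18, a keratin of simple epithelia, went from 37.2 ± 10.5 to 2559 ± 82.8 (log2 change 6.10 ± 0.17 SE, adjusted p = 4.12e-13). The mitochondrially encoded mt-Cytb went from 69147 ± 853 to 10823 ± 1956 (log2 change -2.69 ± 0.14 SE, adjusted p = 2.88e-06). The share of signal in rows of mitochondrial genes was 0.588% and 0.761% in the ETO libraries and 3.34% and 3.39% in the Control libraries.

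The carnitine palmitoyltransferase genes rose in ETO, Cpt1a from 2225 ± 102 to 4379 ± 19.3 (log2 change 0.98 ± 0.06 SE, adjusted p = 1.19e-09) and Cpt2 from 199.6 ± 15.1 to 444 ± 7.99 (log2 change 1.15 ± 0.11 SE, adjusted p = 3.09e-07). Cpt1c rose by 1.26 and the merged row of Chkb and Cpt1b by 2.11 on the log2 scale. Kat8 rose by 0.53 (adjusted p = 0.000796). The largest rises were those of Gpnmb (7.32), Ptgs2 (6.53) and Bhlhe41 (6.53), of Adh7, Car6 and Card14, which lay below the limit of 3 reads in both Control libraries and measured 308 ± 12.3, 213 ± 30.6 and 134 ± 13.9 in ETO, and of Cox6a2 and Tmprss2, which were listed at 0 in both Control libraries and measured 249 ± 21.8 and 123 ± 5.26 in ETO. Gpnmb went from 72.6 ± 4.54 to 11764 ± 16.0, and Ptgs2, a cyclooxygenase, from 8.46 ± 4.18 to 832 ± 54.6. Among the largest falls were those of Lefty2 (-6.38), Lefty1 (-5.57), Lin28a (-4.56), Nkx1-2 (-4.48), T (-4.40) and Mobp (-4.29) and of Nphs1, which went from 88.3 ± 9.68 to near that limit in ETO. Lefty2, a target and inhibitor of Nodal signalling, went from 749 ± 16.8 to 8.34 ± 3.58, and Lin28a, an RNA-binding protein of stem cells, from 1319.8 ± 34.2 to 55.7 ± 11.7. Mobp was counted in a row merged with genes of unknown function.

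Of 36 G1/S and replication genes, 0 rose and 36 fell (0 and 36 adjusted over the list alone), with falls of Rrm2 (-1.27), Ccne1 (-1.65) and Mcm3 (-1.06). The G1/S and replication genes stood below other genes as a list (camera adjusted p = 1.18e-15, adjusted p = 0.0176 with an estimated correlation). Of 35 G2/M genes, 0 rose and 35 fell (0 and 35 adjusted over the list alone), with falls of Kif20a (-1.48), Ube2c (-1.64) and Cenpa (-1.56). The G2/M genes stood below other genes as a list (camera adjusted p = 3.87e-16, adjusted p = 0.04 with an estimated correlation). Of 28 Myc family and Myc target genes, 0 rose and 25 fell (0 and 25 adjusted over the list alone), with falls of Tfrc (-1.27), Pa2g4 (-0.82) and Nop56 (-0.72). The Myc family and Myc target genes stood below other genes as a list (camera adjusted p = 8.3e-08, adjusted p = 0.0286 with an estimated correlation). Of 34 ribosome biogenesis genes, 0 rose and 29 fell (0 and 29 adjusted over the list alone), with falls of Ftsj3 (-1.09), Nop10 (-1.21) and Ubtf (-0.94). The ribosome biogenesis genes stood below other genes as a list (camera adjusted p = 8.96e-09, adjusted p = 0.0286 with an estimated correlation). Of 71 cytosolic ribosomal protein genes, 4 rose and 45 fell (4 and 45 adjusted over the list alone), with falls of Rpl5 (-1.65), Rpl8 (-0.58) and Rpl31 (-1.03). The cytosolic ribosomal protein genes stood below other genes as a list (camera adjusted p = 0.000192, adjusted p = 0.0286 with an estimated correlation). Of 67 nuclear genes of oxidative phosphorylation, 0 rose and 59 fell (0 and 61 adjusted over the list alone), with falls of Atp5a1 (-0.97), Atp5g3 (-1.23) and Atp5b (-0.87). The nuclear genes of oxidative phosphorylation stood below other genes as a list (camera adjusted p = 1.31e-12, adjusted p = 0.0176 with an estimated correlation). Of 23 glycolysis genes, 2 rose and 18 fell (2 and 19 adjusted over the list alone), with falls of Ldha (-2.37), Tpi1 (-2.01) and Pkm (-1.60). The glycolysis genes stood below other genes as a list (camera adjusted p = 1.52e-06, adjusted p = 0.125 with an estimated correlation). Of 24 genes of the TCA cycle, 3 rose and 16 fell (3 and 17 adjusted over the list alone), with falls of Fh1 (-1.01) and Sdhc (-0.94). The genes of the TCA cycle stood below other genes as a list (camera adjusted p = 0.00247, adjusted p = 0.0629 with an estimated correlation). Of 28 genes of the pluripotency network, 3 rose and 23 fell (3 and 23 adjusted over the list alone), with falls of Nanog (-1.24), Tcl1 (-1.52) and Gbx2 (-3.18). The genes of the pluripotency network stood below other genes as a list (camera adjusted p = 2.79e-06, adjusted p = 0.0914 with an estimated correlation). Of 16 Wnt/beta-catenin targets, 0 rose and 12 fell (0 and 12 adjusted over the list alone), with falls of Ccnd1 (-1.89), Notum (-1.80) and Axin2 (-1.46). The Wnt/beta-catenin targets stood below other genes as a list (camera adjusted p = 0.000548, adjusted p = 0.0805 with an estimated correlation). The 4 rows of mitochondrially encoded genes fell, with log2 changes of -2.69 for mt-Cytb, -2.52 for the row of mt-Nd1, mt-Nd2 and both ribosomal RNAs, -2.48 for the row of mt-Atp6 to mt-Nd5 and -2.35 for mt-Nd6, the last 2 from a fit without Released replicate 1. Of the 2 rows tested with all libraries, 0 rose and 2 fell (0 and 2 adjusted over the list alone).

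Of 28 p53 target genes, 23 rose and 2 fell (23 and 2 adjusted over the list alone), with rises of Ddit4 (2.81), Plk2 (2.23) and Mdm2 (1.74). The p53 target genes stood above other genes as a list (camera adjusted p = 2.99e-11, adjusted p = 0.0286 with an estimated correlation). Of 31 ATF4 and amino acid response genes, 20 rose and 5 fell (21 and 5 adjusted over the list alone), with a rise of Ppp1r15a (2.20). The ATF4 and amino acid response genes stood above other genes as a list (camera adjusted p = 3.81e-07, adjusted p = 0.04 with an estimated correlation). Of 40 autophagy and lysosome genes, 29 rose and 8 fell (29 and 9 adjusted over the list alone), with rises of Sqstm1 (2.07), Ctsl (1.25) and Atg9b (2.36). The autophagy and lysosome genes stood above other genes as a list (camera adjusted p = 1.12e-07, adjusted p = 0.0286 with an estimated correlation). Of 19 chaperone and unfolded protein response genes of the endoplasmic reticulum, 10 rose and 4 fell (10 and 4 adjusted over the list alone), with rises of Herpud1 (1.68), Sel1l (1.22) and Atf6 (1.33). The chaperone and unfolded protein response genes of the endoplasmic reticulum stood above other genes as a list (camera adjusted p = 0.0118, adjusted p = 0.129 with an estimated correlation). Of 22 NRF2 and oxidative stress genes, 12 rose and 7 fell (12 and 7 adjusted over the list alone), with rises of Srxn1 (2.94), Gpx2 (1.71) and Hmox1 (1.77). The NRF2 and oxidative stress genes stood above other genes as a list (camera adjusted p = 0.0152, adjusted p = 0.104 with an estimated correlation). Of 8 PPAR target genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with rises of Plin2 (2.78), Pdk4 (1.92) and Fabp3 (0.95). The PPAR target genes stood above other genes as a list (camera adjusted p = 0.00804, adjusted p = 0.197 with an estimated correlation). Of 22 cholesterol synthesis genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with rises of Lss (0.84) and Msmo1 (0.78). The cholesterol synthesis genes stood above other genes as a list (camera adjusted p = 0.000117, adjusted p = 0.052 with an estimated correlation). Of 12 trophectoderm markers, 9 rose and 3 fell (9 and 3 adjusted over the list alone), with rises of Krt19 (4.44), Krt7 (4.21) and Krt8 (3.26). The trophectoderm markers stood above other genes as a list (camera adjusted p = 0.00054, adjusted p = 0.0629 with an estimated correlation). Among the members that fell was Cdx2 (-2.64), a transcription factor of that lineage, named here after its value was seen. Of 16 primitive endoderm markers, 9 rose and 2 fell (9 and 2 adjusted over the list alone), with rises of Gata6 (3.23), Gata4 (2.56) and Sparc (0.75). The primitive endoderm markers stood above other genes as a list (camera adjusted p = 0.0096, adjusted p = 0.162 with an estimated correlation). Of 24 imprinted genes, 12 rose and 5 fell (12 and 5 adjusted over the list alone), with rises of Grb10 (2.17) and Peg10 (1.33). The imprinted genes stood above other genes as a list (camera adjusted p = 0.0179, adjusted p = 0.15 with an estimated correlation). Of 20 germline genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone), with rises of Taf7l (2.78) and Hormad1 (1.37) and a fall of Tuba3a (-1.23). The germline genes stood above other genes as a list (camera adjusted p = 0.0466, adjusted p = 0.253 with an estimated correlation), a call also lost under other scalings.

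Of 23 genes of mitochondrial fatty acid oxidation, 9 rose and 7 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.222), with rises of Acadl (1.53) and Etfdh (1.14). Of 14 genes of peroxisomal fatty acid oxidation, 5 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.787), with a rise of Acox3 (0.62) and a fall of Phyh (-1.59). Of 15 genes of fatty acid synthesis, 7 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.399), with rises of Elovl1 (1.36) and Acss2 (1.21). Of 17 genes of formative and primed pluripotency, 5 rose and 9 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.261), with falls of Etv4 (-2.49) and Dnmt3b (-1.60). Of 11 mesoderm and primitive streak markers, 4 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.992), with rises of Mesp2 (2.86) and Eomes (2.60) and a fall of Cdx1 (-2.49). Of 9 neural markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.795), with a rise of Nes (1.83) and a fall of Stmn2 (-1.29). Of 10 fibroblast and feeder markers, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.605), with a rise of S100a6 (3.80) and a fall of Vim (-1.33). Of 27 cell cycle inhibitors and quiescence genes, 15 rose and 10 fell (15 and 10 adjusted over the list alone, camera adjusted p = 0.0504), with rises of Gadd45a (2.92) and Btg2 (1.69). Of 11 genes of MOF and its MSL and NSL complexes, 3 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.529), with a rise of Msl3 (1.12) and falls of Wdr5 (-0.70) and Phf20 (-0.78). Of 24 genes of other lysine acetyltransferases and deacetylases, 7 rose and 8 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.795), with falls of Hdac1 (-1.40), Hdac7 (-1.62) and Kat6b (-0.58), and its median changed sign with total signal as the factor. Of 19 ERK signalling targets, 7 rose and 11 fell (7 and 11 adjusted over the list alone, camera adjusted p = 0.509), with a rise of Dusp5 (4.84) and a fall of Etv5 (-0.77). Of 14 interferon response genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.795), with a rise of Rsad2 (2.96) and a fall of Ddx58 (-0.90). Of 15 genes of the DNA methylation machinery, 5 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.605), with a rise of Dnmt3a (2.11) and falls of Dnmt3b (-1.60) and Trim28 (-0.80). Eif1a, the 1 measured member of the list of 2-cell-like genes, fell by 0.39 on the log2 scale. The median, the mean and the test did not share a sign for mesoderm markers, ERK targets, interferon response and DNA methylation genes. Over all genes, 9763 passed an adjusted p of 0.05, 4308 rising and 5455 falling, and 3547 of them changed at least 2-fold (2224 rising and 1323 falling). The share of rising genes among the calls was 44.1% as deposited and 58.7% with total signal as the factor, which moved the median of all genes from -0.09 to 0.09.

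**Figure D3:**
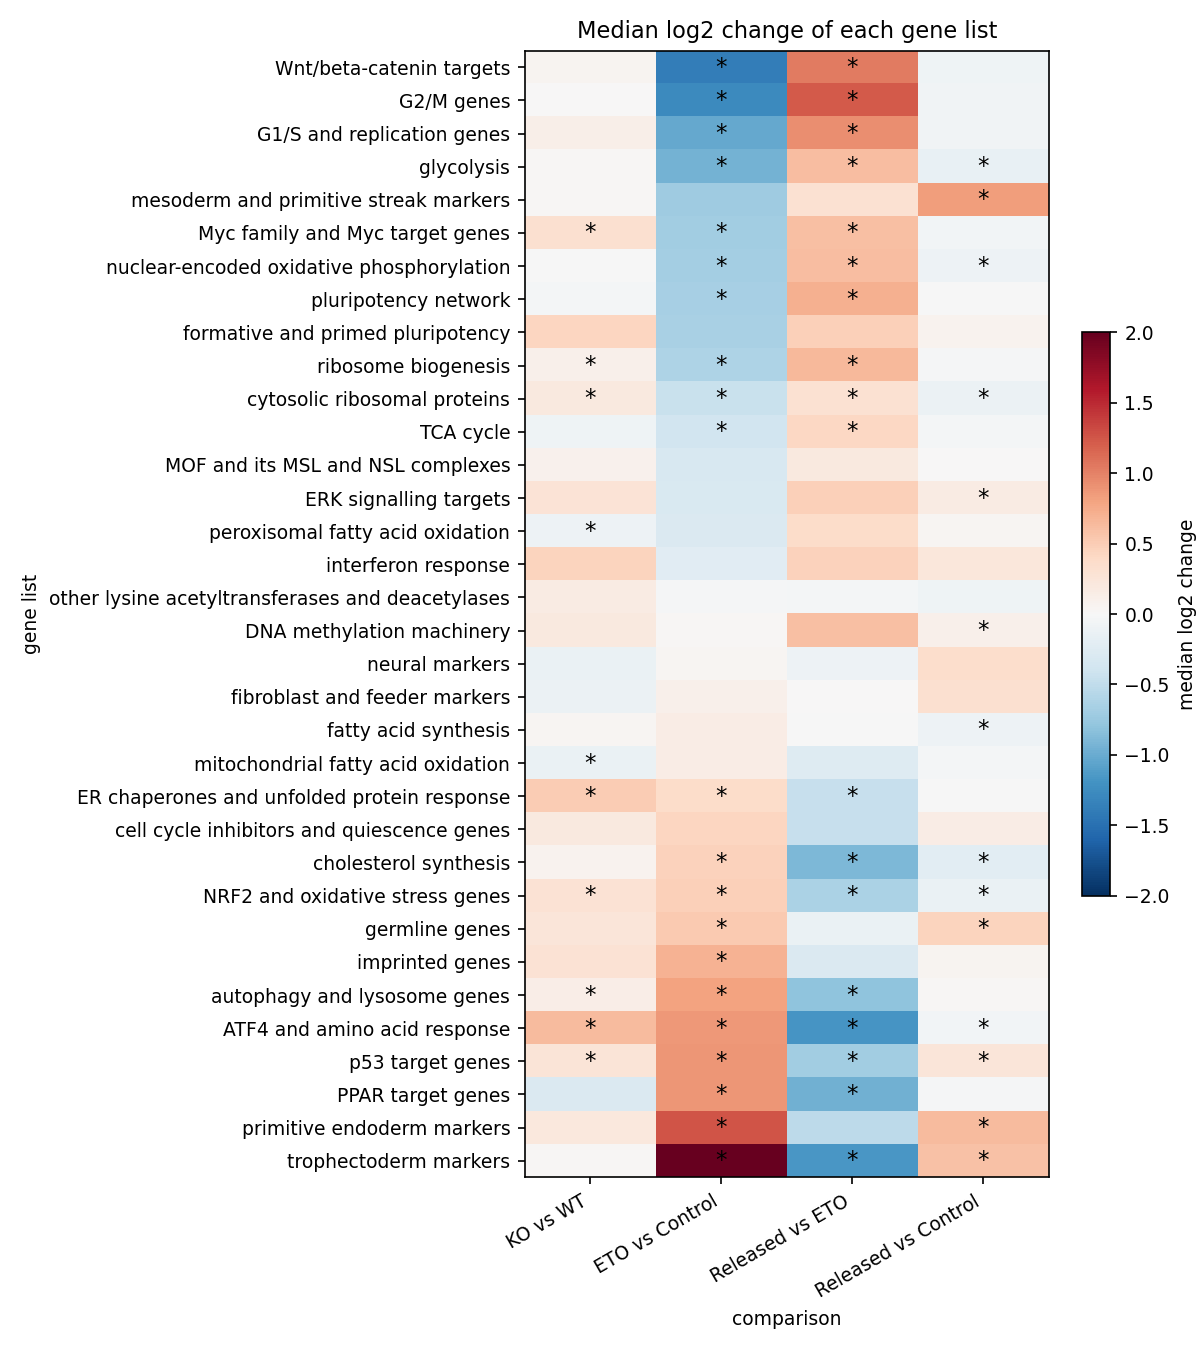
Median log2 change of each of the 34 tested gene lists, as colour, in each of the 4 comparisons, ordered by the ETO against Control median. A star marks a camera adjusted p under 0.05 with the preset correlation. The G2/M list had a median of -1.27 in ETO against Control and 1.22 in Released against ETO.

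Comparing the KO change with the ETO change asks how far the Mof knockout resembles etomoxir treatment. The KO change also holds any effect of hydroxytamoxifen or of Cre activity. The ATF4 target Ppp1r15a rose by 1.22 in KO and 2.20 in ETO, the p53 target Mdm2 by 0.75 and 1.74, and the lysosomal gene Gpnmb by 2.51 and 7.32. Cpt1a fell in KO and rose in ETO, while Nanog rose in KO and fell in ETO. The KO change exceeded the ETO change for 36 of 36 G1/S genes, with the same count adjusted over the list alone (camera adjusted p = 2.01e-15, adjusted p = 0.0107 with an estimated correlation). For 35 of 35 G2/M genes it did so as well, again with the same count (camera adjusted p = 2.96e-15, adjusted p = 0.0344 with an estimated correlation), and for 52 of 67 oxidative phosphorylation genes, 53 adjusted over the list alone (camera adjusted p = 4.08e-09, adjusted p = 0.012 with an estimated correlation). The KO change was lower than the ETO change for 19 of 28 p53 target genes and higher for 1, with 20 and 1 adjusted over the list alone (camera adjusted p = 7.93e-08, adjusted p = 0.0344 with an estimated correlation). It was lower for 26 of 40 autophagy and lysosome genes and higher for 9, with 27 and 9 adjusted over the list alone (camera adjusted p = 2.47e-06, adjusted p = 0.0333 with an estimated correlation). The lists of Myc targets, ribosome biogenesis and ribosomal proteins were also called higher in KO at both correlations. At the preset correlation only, glycolysis, the TCA cycle, the pluripotency network, formative pluripotency and Wnt targets were called higher in KO. Mitochondrial fatty acid oxidation, PPAR targets, cholesterol synthesis, trophectoderm markers and the ATF4 response were called lower in that way. Among the largest differences with a higher KO change were those of Lefty1 (7.88) and Lefty2 (6.28) and of the row of Mir124a-1hg (4.72), which was reversed in the FPKM values (-0.22). Kirrel2 was also among them, and Card14, Fads3, Sorbs3, Tmprss2 and Adh7 were among those with a higher ETO change. For these 6 genes no value is given, because at least 1 library lay below the limit of 3 reads.

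Of the genes called in the KO and ETO comparisons, 1301 rose in both and 809 fell in both, against 1058 and 728 for independent lists of these sizes. Another 1574 rose in KO and fell in ETO, and 492 fell in KO and rose in ETO, against 1340 and 575. In the 3 FPKM settings, genes called in the same direction in both numbered 857, 840 and 613 in all. Across the 16056 genes, which are not independent replicates, the KO and ETO log2 changes had Pearson's r = 0.17 and Spearman's rho = 0.08. The change differed between KO and ETO for 8754 genes, with 5194 higher and 3560 lower in KO. The share of differences higher in KO was 59.3% as deposited, 46.7% with median-of-ratios factors, 46.9% with TMM factors, 48.3% with TMM factors without mitochondrial genes and the 20 highest genes, and 34.5% with total signal. The experiments used different cell lines, so these differences also hold any difference between the lines.

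Released against ETO asks which changes are undone after 4 days without etomoxir. Cell cycle genes rose again: Ccnb2 went from 424 ± 20.6 to 1405 ± 39.3 (log2 change 1.73 ± 0.07 SE, adjusted p = 2.05e-11) and Kif20a, a mitotic kinesin, from 1783 ± 5.93 to 5212 ± 37.3 (log2 change 1.55 ± 0.06 SE, adjusted p = 1.42e-11). Nanog went from 3923 ± 113 to 9064 ± 119 and Lin28a from 55.7 ± 11.7 to 782 ± 25.4. Slc7a11 went from 1120.4 ± 52.4 to 21.5 ± 1.13, Ddit3 from 1509 ± 46.6 to 145 ± 21.4 and Krt18 from 2559 ± 82.8 to 211 ± 4.78 (log2 change -3.60 ± 0.17 SE, adjusted p = 1.26e-10). Cpt1a went from 4379 ± 19.3 to 1912 ± 20.2 (log2 change -1.19 ± 0.06 SE, adjusted p = 1.98e-10), Kat8 fell by 0.58 on the log2 scale, and mt-Cytb rose by 2.75.

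Among the largest rises after release were those of Lefty2 (5.67), T (4.51), Pou2f3 (3.93), Spry4 (3.90), Lin28a (3.80), Nkx1-2 (3.73) and Aire (3.71), and among the largest falls those of Slc7a11 (-5.64) and Ubap1l (-5.05). Cox6a2, Car6, Capn12, Serpinf1 and Inhbe were among the largest falls as well, with at least 1 Released library below the limit of 3 reads, so no value is given. Cpt2 fell by 0.86, Cpt1c by 0.73 and the row of Chkb and Cpt1b by 2.15 on the log2 scale. Of 36 G1/S and replication genes, 36 rose and 0 fell (36 and 0 adjusted over the list alone), with a rise of Cdc6 (1.76). The G1/S and replication genes stood above other genes as a list (camera adjusted p = 3.87e-16, adjusted p = 0.0176 with an estimated correlation). Of 35 G2/M genes, 35 rose and 0 fell (35 and 0 adjusted over the list alone), with a rise of Ube2c (1.64). The G2/M genes stood above other genes as a list (camera adjusted p = 2.46e-16, adjusted p = 0.04 with an estimated correlation). Of 67 nuclear genes of oxidative phosphorylation, 61 rose and 0 fell (61 and 0 adjusted over the list alone), with rises of Atp5a1 (0.87) and Cox6b1 (1.04). The nuclear genes of oxidative phosphorylation stood above other genes as a list (camera adjusted p = 4.62e-12, adjusted p = 0.0176 with an estimated correlation). Of 28 Myc family and Myc target genes, 27 rose and 0 fell (27 and 0 adjusted over the list alone), with a rise of Eif5a (0.77). The Myc family and Myc target genes stood above other genes as a list (camera adjusted p = 5e-08, adjusted p = 0.0286 with an estimated correlation). Of 34 ribosome biogenesis genes, 29 rose and 1 fell (29 and 2 adjusted over the list alone), with a rise of Emg1 (1.08). The ribosome biogenesis genes stood above other genes as a list (camera adjusted p = 1.56e-08, adjusted p = 0.0286 with an estimated correlation). Of 71 cytosolic ribosomal protein genes, 33 rose and 4 fell (33 and 4 adjusted over the list alone), with a rise of Rpl5 (1.36). The cytosolic ribosomal protein genes stood above other genes as a list (camera adjusted p = 0.0133, adjusted p = 0.0629 with an estimated correlation). Of 28 genes of the pluripotency network, 25 rose and 3 fell (25 and 3 adjusted over the list alone), with rises of Utf1 (3.25) and Tcl1 (1.37). The genes of the pluripotency network stood above other genes as a list (camera adjusted p = 3.73e-08, adjusted p = 0.0629 with an estimated correlation). Of 23 glycolysis genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone), with rises of Ldha (1.90) and Pdk1 (2.23). The glycolysis genes stood above other genes as a list (camera adjusted p = 7.4e-05, adjusted p = 0.172 with an estimated correlation). Of 24 genes of the TCA cycle, 15 rose and 3 fell (15 and 3 adjusted over the list alone), with a rise of Fh1 (0.85). The genes of the TCA cycle stood above other genes as a list (camera adjusted p = 0.00859, adjusted p = 0.0823 with an estimated correlation). Of 16 Wnt/beta-catenin targets, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a rise of Axin2 (1.23). The Wnt/beta-catenin targets stood above other genes as a list (camera adjusted p = 0.000755, adjusted p = 0.0823 with an estimated correlation). Of 28 p53 target genes, 3 rose and 22 fell (4 and 22 adjusted over the list alone), with falls of Ddit4 (-2.58) and Mdm2 (-1.34). The p53 target genes stood below other genes as a list (camera adjusted p = 3.25e-08, adjusted p = 0.04 with an estimated correlation). Of 31 ATF4 and amino acid response genes, 4 rose and 24 fell (4 and 25 adjusted over the list alone), with a fall of Trib3 (-2.68). The ATF4 and amino acid response genes stood below other genes as a list (camera adjusted p = 1.47e-10, adjusted p = 0.0286 with an estimated correlation). Of 40 autophagy and lysosome genes, 7 rose and 27 fell (7 and 27 adjusted over the list alone), with falls of Gpnmb (-4.46) and Sqstm1 (-2.18). The autophagy and lysosome genes stood below other genes as a list (camera adjusted p = 3.61e-08, adjusted p = 0.0286 with an estimated correlation). Of 22 cholesterol synthesis genes, 1 rose and 17 fell (1 and 17 adjusted over the list alone), with a fall of Cyp51 (-1.15). The cholesterol synthesis genes stood below other genes as a list (camera adjusted p = 4.43e-08, adjusted p = 0.0286 with an estimated correlation). Of 22 NRF2 and oxidative stress genes, 7 rose and 15 fell (7 and 15 adjusted over the list alone), with falls of Srxn1 (-3.18) and Gpx2 (-2.09). The NRF2 and oxidative stress genes stood below other genes as a list (camera adjusted p = 0.000629, adjusted p = 0.052 with an estimated correlation). Of 19 chaperone and unfolded protein response genes of the endoplasmic reticulum, 3 rose and 11 fell (4 and 11 adjusted over the list alone), with a fall of Herpud1 (-1.82). The chaperone and unfolded protein response genes of the endoplasmic reticulum stood below other genes as a list (camera adjusted p = 0.00345, adjusted p = 0.0914 with an estimated correlation). Of 12 trophectoderm markers, 3 rose and 9 fell (3 and 9 adjusted over the list alone), with falls of Krt19 (-3.81), Krt7 (-3.17) and Krt8 (-2.03). The trophectoderm markers stood below other genes as a list (camera adjusted p = 0.00218, adjusted p = 0.0823 with an estimated correlation). Of 8 PPAR target genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone), with a fall of Plin2 (-2.91). The PPAR target genes stood below other genes as a list (camera adjusted p = 0.00698, adjusted p = 0.192 with an estimated correlation).

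The other 16 tested lists were not called in this comparison, among them formative pluripotency genes, of which 9 rose and 3 fell of 17 (9 and 3 adjusted over the list alone). Over all genes, 9262 passed an adjusted p of 0.05, 5315 rising and 3947 falling, and 3051 of them changed at least 2-fold (1314 rising and 1737 falling). The share of rising genes was 57.4% as deposited and 45.0% with total signal. The median, the mean and the test did not share a sign for fibroblast markers and for other acetyltransferases and deacetylases, and the fibroblast median changed sign with total signal.

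**Figure D4:**
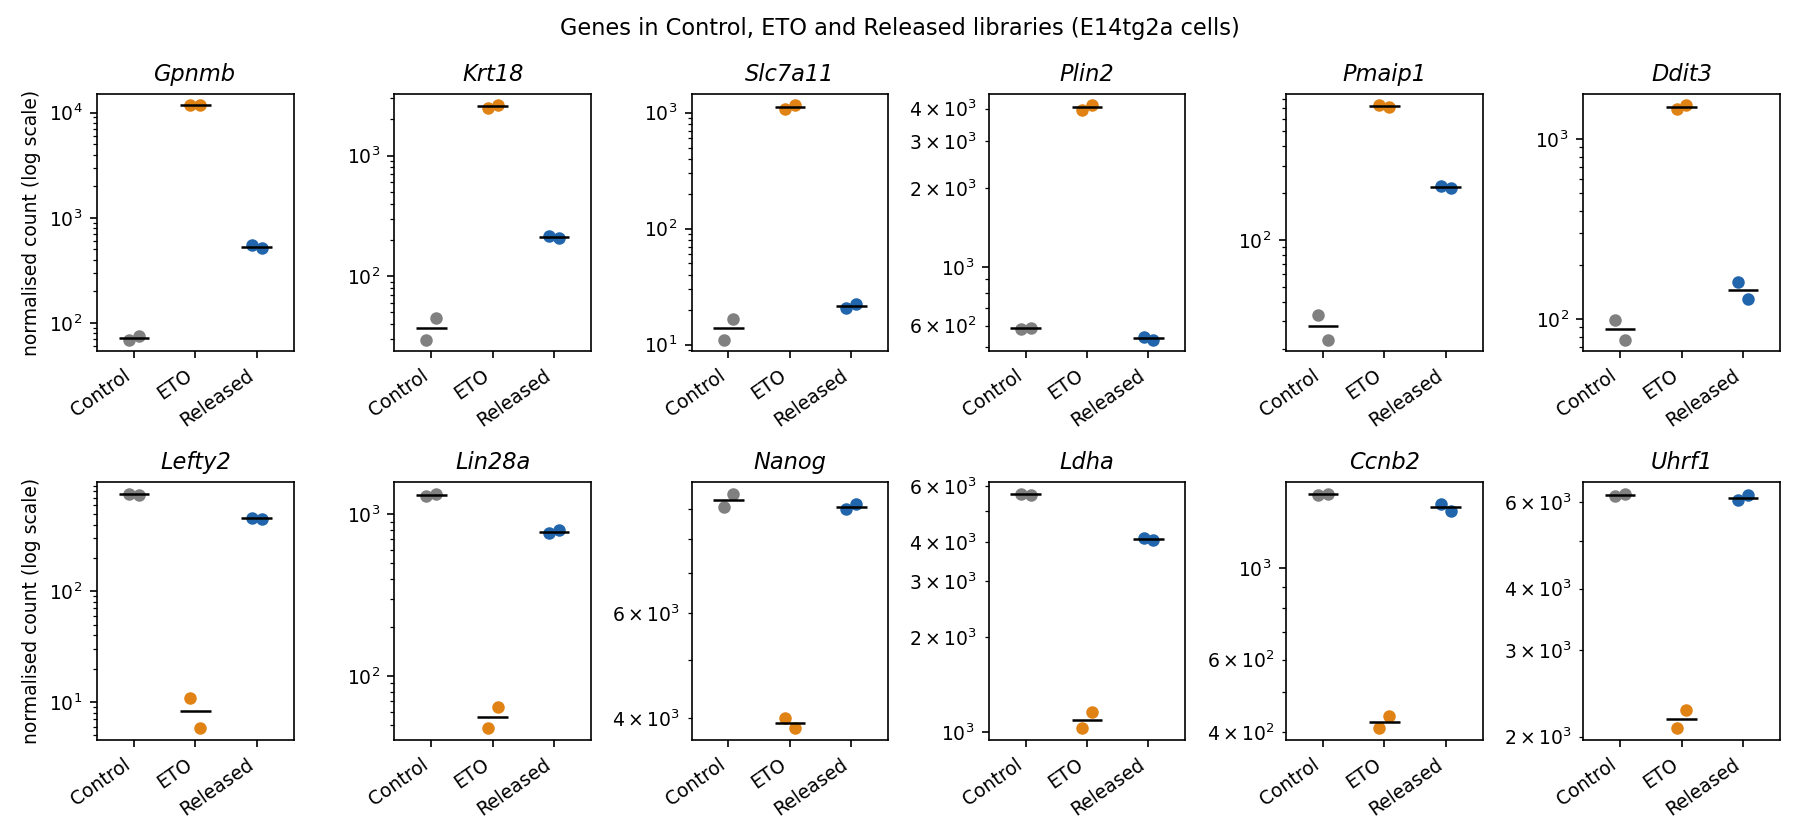
Normalised counts on a log scale of 12 genes in the Control, ETO and Released libraries, as points, with a line at the mean of each group (n = 2). Gpnmb had means of 72.6 in Control, 11764 in ETO and 532 in Released.

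Released against Control asks what remains after release, and no Control for the release period is named in the labels. Gpnmb stayed above Control, at 532 ± 26.6 against 72.6 ± 4.54 (log2 change 2.86 ± 0.09 SE, adjusted p = 9.11e-11). Pmaip1 measured 219 ± 4.34 against 27.9 ± 7.21 (2.95), and Krt18 211 ± 4.78 against 37.2 ± 10.5 (2.50). Lefty1 stayed below, at 58.5 ± 4.88 against 262 ± 10.2 (-2.15). The imprinted genes H19 and Igf2 were higher, by 3.33 and 3.04, as was Xist, the RNA of X inactivation, by 2.64, with its row overlapped by the antisense gene Tsix. Of 24 imprinted genes, 7 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.605). The other largest rises were those of Ptgs2 (2.84), Nectin4 (2.79) and Dusp8 (2.56), and among the largest falls were those of Lrrc15 (-2.25), Ap3b2 (-1.74), S100a13 (-1.47), Calb2 (-1.42), Ephb1 (-1.36) and Smim19 (-1.34). In the FPKM values, Igf2, Xist, Ptgs2, Dusp8 and Ephb1 were not called, H19 was called under 1 of 3 FPKM settings, and Ephb1 was not called without Control replicate 1 or 2 or Released replicate 2. Kat8 measured 367 ± 40.0 against 378 ± 7.81 (log2 change -0.05, adjusted p = 0.846) and mt-Cytb 72327 ± 2976 against 69147 ± 853 (0.06, adjusted p = 0.82). Cpt1a fell by 0.22 on the log2 scale (adjusted p = 0.0221), a call lost without any 1 of the Control and Released libraries, with total signal and in the FPKM values.

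Of 28 p53 target genes, 13 rose and 0 fell (18 and 0 adjusted over the list alone), with rises of Plk2 (0.83), Btg2 (0.70) and Perp (1.22). The p53 target genes stood above other genes as a list (camera adjusted p = 2.99e-11, adjusted p = 0.0286 with an estimated correlation). Of 12 trophectoderm markers, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with a rise of Krt8 (1.23). The trophectoderm markers stood above other genes as a list (camera adjusted p = 2.65e-05, adjusted p = 0.0431 with an estimated correlation). Of 22 cholesterol synthesis genes, 0 rose and 9 fell (0 and 13 adjusted over the list alone), with a fall of Insig1 (-0.50). The cholesterol synthesis genes stood below other genes as a list (camera adjusted p = 1.25e-08, adjusted p = 0.0286 with an estimated correlation). Of 71 cytosolic ribosomal protein genes, 1 rose and 11 fell (1 and 12 adjusted over the list alone), with a fall of Rpl4 (-0.22). The cytosolic ribosomal protein genes stood below other genes as a list (camera adjusted p = 0.000407, adjusted p = 0.0292 with an estimated correlation). Of 23 glycolysis genes, 0 rose and 7 fell (1 and 9 adjusted over the list alone), with a fall of Ldhb (-1.14). The glycolysis genes stood below other genes as a list (camera adjusted p = 3.07e-06, adjusted p = 0.129 with an estimated correlation). Of 67 nuclear genes of oxidative phosphorylation, 0 rose and 5 fell (0 and 3 adjusted over the list alone), with a fall of Uqcrc2 (-0.24). The nuclear genes of oxidative phosphorylation stood below other genes as a list (camera adjusted p = 0.00263, adjusted p = 0.0629 with an estimated correlation). Of 20 germline genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a rise of Dnmt3l (1.54). The germline genes stood above other genes as a list (camera adjusted p = 0.000124, adjusted p = 0.0805 with an estimated correlation). Of 19 ERK signalling targets, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a rise of Etv4 (0.55). The ERK signalling targets stood above other genes as a list (camera adjusted p = 0.00417, adjusted p = 0.172 with an estimated correlation). Of 16 primitive endoderm markers, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with a rise of Col4a1 (1.48). The primitive endoderm markers stood above other genes as a list (camera adjusted p = 0.00592, adjusted p = 0.141 with an estimated correlation). Of 15 genes of the DNA methylation machinery, 4 rose and 0 fell (6 and 1 adjusted over the list alone), with rises of Dnmt3l (1.54), also on the germline list, and Tet2 (0.69). The genes of the DNA methylation machinery stood above other genes as a list (camera adjusted p = 0.0196, adjusted p = 0.328 with an estimated correlation). Of 22 NRF2 and oxidative stress genes, 2 rose and 7 fell (5 and 11 adjusted over the list alone), with a fall of Gpx2 (-0.38). The NRF2 and oxidative stress genes stood below other genes as a list (camera adjusted p = 0.0231, adjusted p = 0.125 with an estimated correlation), a call also lost with total signal as the factor. Of 11 mesoderm and primitive streak markers, 2 rose and 0 fell (4 and 0 adjusted over the list alone), with a rise of Mesp2 (2.25). The mesoderm and primitive streak markers stood above other genes as a list (camera adjusted p = 0.0267, adjusted p = 0.129 with an estimated correlation), a call also lost with total signal. Of 31 ATF4 and amino acid response genes, 4 rose and 10 fell (7 and 11 adjusted over the list alone), with a fall of Psat1 (-0.46). The ATF4 and amino acid response genes stood below other genes as a list (camera adjusted p = 0.037, adjusted p = 0.22 with an estimated correlation), also lost with total signal. Of 15 genes of fatty acid synthesis, 1 rose and 4 fell (1 and 4 adjusted over the list alone), with falls of Scd1 (-0.39) and Fads1 (-0.46). The genes of fatty acid synthesis stood below other genes as a list (camera adjusted p = 0.0458, adjusted p = 0.251 with an estimated correlation), lost with total signal too. Of 36 G1/S and replication genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.066). Of 35 G2/M genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.0776). Of 28 genes of the pluripotency network, 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.411), with a rise of Utf1 (1.37) and a fall of Lin28a (-0.75). The median, the mean and the test did not share a sign for PPAR targets, the pluripotency network and chaperone genes, and the medians of these lists changed sign with total signal, as did those of mitochondrial fatty acid oxidation and ribosome biogenesis. The other 17 tested lists were not called. In the FPKM values Rpl4, Uqcrc2, Col4a1, Etv4 and Tet2 were not called, nor was Rpl4 without Control replicate 1 or Released replicate 1, or Uqcrc2 without any 1 of the Control and Released libraries.

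Over all genes, 2012 passed an adjusted p of 0.05 in Released against Control, 1128 rising and 884 falling, and 508 of them changed at least 2-fold (431 rising and 77 falling). The count was 770 without Released replicate 2 and 828 without Released replicate 1, 882 and 896 without Control replicate 1 or 2, and 292 in the FPKM values. In a fit per experiment 3662 genes were called, and with a replicate block 3110. The share of rising genes was 56.1% as deposited, 70.0% with total signal and 49.2% after the trend of each library with gene length and GC content was removed, with 1361 rising and 1405 falling. Of the 9763 genes called in ETO against Control, 7925 (81.2%) were called in the opposite direction in Released against ETO, and 6797 (69.6%) were so called and not called against Control. These comparisons share the ETO libraries, which gives opposite changes without any effect: Pearson's r across genes was -0.88, against -0.50 for simulated unchanged groups (covariance -0.948 against -0.0441). With 1 ETO library for each, 6591 of 8594 and 6430 of 8674 ETO calls (76.7% and 74.1%) were called in the opposite direction. Of the same 9763 genes, 1324 (13.6%) were still called against Control in the direction of the ETO change, and 299 were called in the other direction, groups that overlap with the 7925. The count of 1324 was 545 and 557 without Released replicate 2 or 1, 638 and 633 without Control replicate 1 or 2, 195 in the FPKM values and 2322 in a fit per experiment. The comparisons with Control share its libraries: Pearson's r across genes was 0.55, against 0.50 for simulated unchanged groups (covariance 0.325 against 0.0448). With a different Control library for each, 681 and 643 genes were still called in the same direction, of 8614 and 8601 ETO calls, and with 1 and the same Control library for both, 681 and 709 were. The lower counts thus come mostly from the use of 1 library. Among the genes chosen by their largest ETO change that were still called were Lefty2 (-0.71), Nphs1 (-0.91), Lin28a (-0.75) and Nkx1-2 (-0.75) and Adh7, with Adh7, Lefty2, Nphs1 and Lin28a not called in the FPKM values. Lefty2 and Nkx1-2 were not called without any 1 of the Control and Released libraries, Nphs1 not without Released replicate 2 or either Control replicate, and Adh7 not without Released replicate 2. Cox6a2 and Tmprss2, listed at 0 in Control, measured 1.96 ± 1.12 and 24.4 ± 6.37 in Released, the first below the limit that 3 reads allow. Over the 3547 genes with an ETO change of at least 2-fold, the slope of the Released change on the ETO change, each with its own Control library, was 26.7% and 26.4%. Another 389 genes were called only against Control after release and not in ETO, a count in which the difference itself was not tested.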

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

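The plain TMM factors, the pseudocounts of 0.5 and 5, the repeated names kept apart, the mitochondrial rows kept with their 0, the separate ETO libraries and the length and GC correction were chosen after the results were seen. Over all alternatives, 407 of 492 counts stayed within 1.5 times and 85 moved further. A similar count can hold other genes. With total signal, 4315 of the 6086 KO against WT calls (70.9%) stayed called in the same direction. In log2(FPKM + 1) with FPKM above 1, 2658 of 5831 (45.6%) did so, and 255 of 1901 (13.4%) for Released against Control. Of 1088 results for gene lists, 963 kept direction and side of the threshold, 63 gained a call and 62 lost one. Of the lost calls, 38 were with an estimated correlation, 8 with total signal, 7 after the length and GC correction and 3 in a fit per experiment. Not all of these are named beside the lists above. Of 16205 results for named genes, 15143 were kept, 84 gained and 970 lost a call, and 8 reversed. Most named genes were picked for a small p or a large change in these same data. Some alternatives left out a library outside the comparison. Agreement was thus in part fixed in advance. Where a cause is not stated, the cause was not tested. With a change of at least 2-fold also asked, which by construction calls fewer genes, 1088 genes were called for KO against WT, 3547 for ETO against Control, 3051 for Released against ETO, 508 for Released against Control and 3990 for the difference between KO and ETO changes. The same threshold left 369 genes called in the same direction in KO and ETO, 383 still called after release and 2414 called the other way in Released against ETO. A fit per experiment, which the difference does not have, called 3662 genes for Released against Control and left 2322 still called. For KO against WT the same fit called fewer genes, 2842 rising and 1541 falling, against 3944 and 2142 in the main fit. Replicate numbers did not pair samples (correlations of deviations -0.0362 to 0.0812), and a replicate block gave 3110 and 1999. In log2(FPKM + 1) with FPKM above 1, the counts were 2906 for KO against WT, 292 for Released against Control, 857 shared and 195 still called. With log2(FPKM + 0.1) these were 2835, 265, 840 and 186, and 5684 for the difference. Without a filter they were 2196, 216, 613 and 134, with 5433 for the difference and 5180 called the other way. In these 3 FPKM settings Col4a2 in KO against WT reversed to -0.23, -0.51 and -0.23, and Kansl1 to -0.0192, -0.0174 and -0.0192. Mir124a-1hg in the difference reversed to -0.22 in the first and the last. With separate Control libraries, 681 and 643 genes were still called after release, and with separate ETO libraries 6591 and 6430 were called the other way. Of the list tests, 25 were called with an estimated correlation and 110 by fry, against 63. Leaving out 1 library, where the lone sample of a group is assumed to vary like the others and a group has fewer samples, gave 4635 to 5912 calls for KO against WT, 8357 to 10161 for ETO against Control, 7554 to 9685 for Released against ETO and 7702 to 8668 for the difference. The range was 1706 to 2038 for shared calls and 6663 to 8338 for calls the other way. Released against Control ranged from 770 without Released replicate 2 to 2864 without WT replicate 2, with 828 without Released replicate 1 and 882 and 896 without Control replicates 1 and 2. Still called genes ranged from 545 without Released replicate 2 to 1844 without WT replicate 1, with 557 without Released replicate 1 and 638 and 633 without Control replicates 1 and 2. Falling genes in Released against Control, 884 with all libraries, were 1339 and 1338 without WT replicates 1 and 2. They were 280 and 328 without Control replicates 1 and 2, and 358 and 316 without Released replicates 1 and 2. After the length and GC correction they were 1405. Rising genes, 1128 with all libraries, were 602 and 568 without Control replicates 1 and 2, and 470 and 454 without Released replicates 1 and 2. The DESeq2 Wald test, the edgeR quasi-likelihood test and filterByExpr were not run, since the deposited values are not whole read counts. Reads estimated from the factor of each library were not tried in these tests. In data simulated with the same spread in all groups, 52.3% of 1.5-fold changes were recovered for KO against WT and 11.4% of the calls were false.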

Other observations

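The tests of gene length and GC content, of scaling for the lists, of a lower share of stem cells, of trophectoderm cells and of a share of cells without a Y chromosome were chosen after the result was seen. The test of gene length and GC content was also revised after its first result, in which the ribosomal call was not kept. The test of a lower share of stem cells was changed from list medians to a permutation of means before its p was seen. On the X chromosome, the median log2 change was -0.26 over 621 genes in ETO against Control, against -0.09 over all genes, with 103 rising and 239 falling. On chromosome 14, the median was -0.11 over 466 genes in Released against Control, with 34 rising and 78 falling. On chromosome 19, it was 0.03 over 482 genes in ETO against Control, with 149 rising and 148 falling. In Released against ETO, it was 0.21 on the X chromosome and -0.06 on chromosome 19, against 0.10 over all genes. These were found in a scan of all chromosomes and not tested further.

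The lists of oxidative phosphorylation, ribosomal proteins, G1/S and G2/M were lower in ETO than in Control. After the trend of each library with gene length and GC content was removed, 73.2%, 64.3%, 102% and 105% of their medians were kept, and the camera adjusted p was 1.39e-08, 0.0314, 5.41e-16 and 1.54e-16. The lowest value, 64.3%, argues against that trend as the whole cause, though it may account for a part for the first 2 lists. Another scaling moved the median of all genes by at most 0.182, less than the change of any of the 4 medians, the nearest being -0.45. Etomoxir treatment, as the design gives it, stays open with cell density and growth rate, which were not tested.

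Keratins and other trophectoderm markers were higher in ETO, while Cdx2 (-2.64), Tfap2a (-0.59) and Tead4 (-0.33) fell. The test of a lower share of embryonic stem cells assumed that it would raise markers of other cell types alike. The mean log2 change was 1.87 over 12 trophectoderm markers and 0.39 over 30 mesoderm, neural and fibroblast markers (two-sided permutation test of the means, with genes taken as independent, p = 0.0516). Markers need not rise alike, since that depends on which other cells are present and on each marker's level in stem cells. The test thus cannot decide, and that explanation stays open. The 16 primitive endoderm markers, which were outside that set, had a mean log2 change of 1.26. For trophectoderm cells, 3 of 12 markers fell, and the Control libraries also express these 3 genes, so it stays open too. The labels name no sort that would remove such cells.

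The Y-linked genes with a Control mean of at least 100 were lower in Released than in Control, Ddx3y by -0.72, Eif2s3y by -0.80 and Uty by -0.67, as found in the scan of chromosomes. Another scaling moved the median of all genes by at most 0.0454, which argues against scaling. The summed X-linked partners did not gain what the Y-linked genes lost (-214% of the loss). Ddx3x dominates that sum, from 10783 to 8962, and was itself called as falling (adjusted p = 0.0236). Its own change could hide reads moved to it, so the test cannot decide that explanation. The partners Eif2s3x (-0.18) and Kdm6a (-0.11) were not called. On the X chromosome, 29 genes rose and 64 fell in this comparison. The chi-square test of heterogeneity found no difference between the changes of the 3 Y-linked genes beyond error (p = 0.735). A share of the released cells without a Y chromosome remains a candidate explanation. It was found and tested on the same 3 genes, so passing that test gives it little support. Against a simple account, Eif2s3y was already at -0.81, Uty at -0.34 and Ddx3y at -0.14 (not called) in ETO against Control, the 3 changed by 0.01 (not called), -0.33 and -0.58 in Released against ETO, and Uba1y and Zfy1, near the floor, did not fall, Zfy1 being called as rising (adjusted p = 0.0426).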
